A study of Mus musculus with 12 samples.

How the data were processed

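Gene expression was measured in whole kidneys of mice at 6 months of age, on 12 arrays, 1 array per mouse. The 4 groups of 3 arrays combined diabetes with the D6 genotype. D6 is the product of Ackr2, an atypical chemokine receptor that binds inflammatory CC chemokines and removes them without signalling to the cell. FVB mice were non-diabetic with intact D6, D6 mice were non-diabetic D6 knockouts, OVE mice carried the OVE26 transgene, which causes diabetes early in life, and OVE-D6 mice were diabetic D6 knockouts. Per the labels, the knockout allele was crossed into FVB for at least 10 generations before the cross to OVE mice. The number of arrays per group limits the precision.

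Per the labels' protocols, 100 ng of RNA with an integrity number above 8.8 (average 9.1) was amplified and labelled with whole-transcript kits and hybridised to Affymetrix mouse gene arrays. The deposited values were log2 probe-set summaries, 1 per probe set and array. The array medians lay close together, between 6.84 and 6.93, so the table was used as already normalised between arrays. The summarisation and normalisation method was not given in the sources used here, and no further scaling was applied. No per-sample column was left unmapped.

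The table held 35556 probe sets. The platform annotation was updated through the mouse gene table of assembly GRCm38.p6, which was used for names and gene order alone. Of the probe sets, 21789 had 1 gene symbol, 1621 had several and 12146 were not named here. Symbols were taken through the Entrez identifier for 21698 probe sets and through an accession for 3, and 88 platform symbols were kept. For the 1001 genes with several probe sets, the probe set with the highest mean over all arrays stood for the gene. This gave 19936 genes, of which 16480 lay above the array's own 25th percentile on at least 3 arrays and were tested. Genes without a single-symbol probe set were not analysed here.

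The test was limma 3.58.1 in R 4.3.3, with lmFit over all 12 arrays in a group-means model, contrasts, eBayes with default settings and Benjamini-Hochberg adjustment at an adjusted p of 0.05. There were 6 comparisons. These were OVE against FVB, OVE-D6 against OVE, D6 against FVB, OVE-D6 against D6, the interaction (the diabetes effect in knockouts minus that in wild types), and the knockout effect averaged over disease state. Fold changes are differences of log2 means, with the standard error from the moderated variance. Means and differences are given on the log2 scale.

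The 35 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Lists with at least 5 tested members, 33 of them, were tested with camera at its preset correlation between genes of 0.01, with adjustment over the lists. Camera with an estimated correlation and fry were alternatives. In each comparison, the text names Ackr2, up to 6 genes that rose and 6 that fell most among those past the threshold whose 2 groups did not overlap, and up to 4 members past the threshold of each list. The overlap condition was not used for the interaction and the averaged contrast. Where fewer than 5 genes passed, the 8 genes with the smallest p were also named, as not passing. Unnamed and predicted genes were left out of the rule. Members of the D6-scavenged chemokines and of the genes beside Ackr2 could be named whether or not they passed, and check genes of the sex chromosomes could be given as values.

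The size of the diabetes effect in the 2 genotypes was compared over genes chosen on the average diabetes effect. That effect is orthogonal to the interaction where the groups vary alike, but the median SD over genes was 0.123 in OVE and 0.096 to 0.105 in the other groups. The test was a two-sided permutation of the genotype within each disease state, called exact because it ran over all assignments. The genes were chosen once, with the real labels, so its p can lean towards the real split. Alternatives changed the filter, the normalisation, the probe set per gene, the variance model, the arrays in the fit and the threshold, added the replicate number as a block, and left out each array in turn. The alternative of another pseudocount did not apply to log2 values. Leaving the genes beside Ackr2 out of the OVE-D6 against OVE comparison and of the lists was chosen after seeing the data.

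The scripts were tested on simulated data with 200 changed genes among 16480, in 20 runs per comparison. For OVE-D6 against OVE, 80.9% of genes changed 1.5-fold and 97.8% of genes changed 2-fold were recovered, with 5.32% false calls. For the interaction these shares were 39.6% and 88.7%. The simulated noise was independent between genes and alike in all groups, so these shares need not hold for the real arrays. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.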

Results

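Whole-kidney expression was compared across the 4 groups of 3 mice to ask how diabetes altered the kidney and whether loss of the chemokine-scavenging receptor D6 altered that response. In a principal component analysis of the 16480 tested genes, the first component held 35.9% of the variance. OVE replicates 1 and 2 lay at 27.0 and 29.4 on it, OVE replicate 3 at 6.9, and the other 9 arrays between -15.1 and 5.2. OVE replicate 3 thus lay closer to the non-diabetic arrays than the other OVE arrays did.

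**Figure D1:**
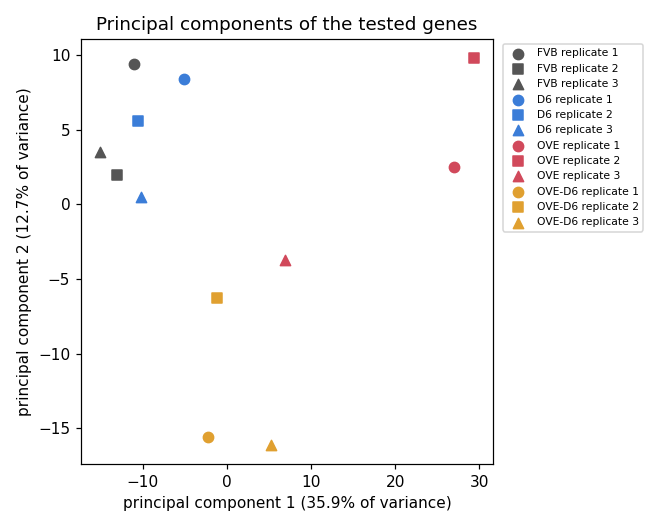
Principal components 1 (horizontal) and 2 (vertical), in log2 units, of the 16480 tested genes, with 1 point per array, coloured by group and shaped by replicate. OVE replicates 1 and 2 lie at 27.0 and 29.4 on component 1 and OVE replicate 3 at 6.9.

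Ackr2 itself, the gene removed in the knockouts, had similar values in all groups. Its log2 value lay between 6.74 and 7.04 on the 12 arrays, and it differed by -0.10 ± 0.08 (SE, n = 3 per group) between D6 and FVB and by 0.03 ± 0.08 between OVE-D6 and OVE. Neither difference passed the limma test (adjusted p = 1 and 0.899). A probe set outside the deleted part checks nothing, and which part was deleted was not used here. Slc6a20b, a neutral amino acid transporter gene near Ackr2 on chromosome 9, lay between 11.13 and 11.26 on the 6 knockout arrays and between 11.96 and 12.59 on the 6 wild-type arrays.

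**Figure D2:**
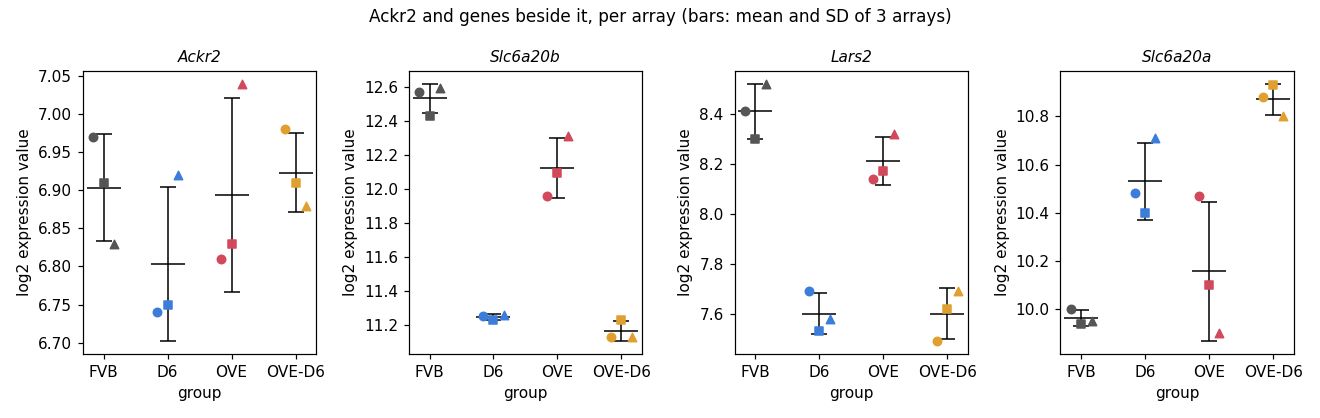
Log2 expression values (vertical axis, a separate range per panel that does not start at 0) of Ackr2, Slc6a20b, Lars2 and Slc6a20a on each array by group, with bars for the mean and SD of 3 arrays. Slc6a20b lies at or below 11.26 on all 6 knockout arrays and at or above 11.96 on all 6 wild-type arrays, while Ackr2 lies between 6.74 and 7.04 on all arrays.

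Diabetes with intact D6 changed the kidney widely. Markers of tubular injury rose, led by Lcn2, the neutrophil gelatinase-associated lipocalin, at 13.6-fold in OVE over FVB (log2 3.76 ± 0.53, SE, n = 3 per group, adjusted p = 0.00341), and Havcr1, the kidney injury molecule, at 4.71-fold (log2 2.24 ± 0.35). Macrophage genes rose as well, with the lysozyme gene Lyz2 6.88-fold and the phagocyte marker Cd68 3.24-fold higher. Cyp27b1, the enzyme that activates vitamin D, was 6.08-fold higher (log2 2.60 ± 0.23, adjusted p = 0.000393), and Serpina3n, an acute-phase protease inhibitor, was 4.79-fold higher. Genes that fell most were Slc22a26, an organic anion transporter gene (log2 -1.66 ± 0.30), Esm1, an endothelial proteoglycan gene (log2 -1.27 ± 0.25), Fcamr, an Fc receptor gene (log2 -1.26 ± 0.14), and Nepn (log2 -1.25 ± 0.22).

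Of the 21 tested macrophage and monocyte markers, 17 rose and none fell (20 adjusted over the list alone), with a median log2 change of 1.30 and a camera adjusted p of 1.68e-17 (adjusted p = 0.178 with an estimated correlation). Of 18 tubular injury markers 11 rose (17 adjusted over the list alone), among them the adhesion receptor Cd44 at 3.46-fold and the keratin gene Krt20 at 3.63-fold, with a median of 0.78 and adjusted p = 1.09e-14 (adjusted p = 0.178 with an estimated correlation). Extracellular matrix genes rose in 17 of 30 cases (28 adjusted over the list alone), including the protease inhibitor gene Timp1 at 3.69-fold, the collagen cross-linking enzyme Lox at 3.42-fold and fibronectin, Fn1, at 2.57-fold. Their median was 0.67 (adjusted p = 1.98e-17, and adjusted p = 0.178 with an estimated correlation). Cell cycle genes rose in 13 of 19 cases (18 adjusted over the list alone), including Mki67, a proliferation marker, at 2.35-fold, Mcm6 at 2.35-fold and Ccna2 at 2.30-fold, with a median of 0.77 (adjusted p = 2.17e-13, and adjusted p = 0.178 with an estimated correlation).

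Among 8 tested CC chemokines that D6 scavenges, 5 rose (5 adjusted over the list alone). They were Ccl2, the main monocyte attractant, at 3.75-fold (log2 1.91 ± 0.32, adjusted p = 0.00674), Ccl5 at 2.34-fold, Ccl17 at 2.15-fold, Ccl7 at 1.83-fold and Ccl3 at 1.58-fold. Ccl11, Ccl22 and Ccl4 had log2 differences of 0.27, 0.21 and 0.02 and did not pass. The list had a median of 0.77 and adjusted p = 3.99e-05 (adjusted p = 0.201 with an estimated correlation). Of 16 other chemokines 8 rose (10 adjusted over the list alone), with Ccl28 4.53-fold, Cxcl10 3.79-fold, Cxcl13 3.38-fold and Ccl9 3.19-fold higher, and adjusted p = 1.36e-06 (adjusted p = 0.178 with an estimated correlation). Complement genes rose in 8 of 12 cases and fell in 1 (9 and 1 adjusted over the list alone), with C7 3.77-fold and C3ar1, the C3a receptor gene, 2.79-fold higher, and adjusted p = 2.89e-06 (adjusted p = 0.178 with an estimated correlation).

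Of 23 fatty acid oxidation and PPAR alpha target genes 7 rose (10 adjusted over the list alone), including the lipase inhibitor Angptl4 at 3.25-fold and Pdk4, a kinase that restrains glucose oxidation, at 2.43-fold, with adjusted p = 0.00012 (adjusted p = 0.248 with an estimated correlation). Of 23 loop, distal tubule and collecting duct markers 6 fell (8 adjusted over the list alone), among them Pvalb (log2 -0.84 ± 0.10), the anion exchanger gene Slc26a4 (log2 -0.75 ± 0.12), the water channel gene Aqp4 (log2 -0.74 ± 0.16) and Egf (log2 -0.69 ± 0.12). Their median was -0.14 (adjusted p = 0.00305, and adjusted p = 0.178 with an estimated correlation). Of 19 cholesterol and fatty acid synthesis genes 1 fell, the regulator Srebf1 (log2 -0.46 ± 0.12), and 9 fell and 1 rose adjusted over the list alone, with adjusted p = 0.00128 (adjusted p = 0.201 with an estimated correlation). Nphs1, which encodes nephrin of the podocyte slit diaphragm, fell by 0.62 ± 0.13 on the log2 scale, while the list of 16 podocyte markers did not pass (adjusted p = 0.519).

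In all, 808 genes were higher and 392 lower in OVE than in FVB, 1200 of 16480, with 3967 at an unadjusted p under 0.05 where chance gives 824. The groups did not overlap in 27.1% of genes (chance 10%). The count was 670, 476 and 422 without FVB replicate 1, 2 or 3, and 708, 353 and 1896 without OVE replicate 1, 2 or 3. A fit of these 2 groups alone gave 440. The FVB means of Krt20, Timp1, Ccl2 and Mcm6, at 4.93, 5.71, 5.88 and 5.93, lay at or under 5.93, the 95th percentile of 1027 olfactory receptor genes, which kidney should hardly express, so their folds are not exact.

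**Figure D3:**
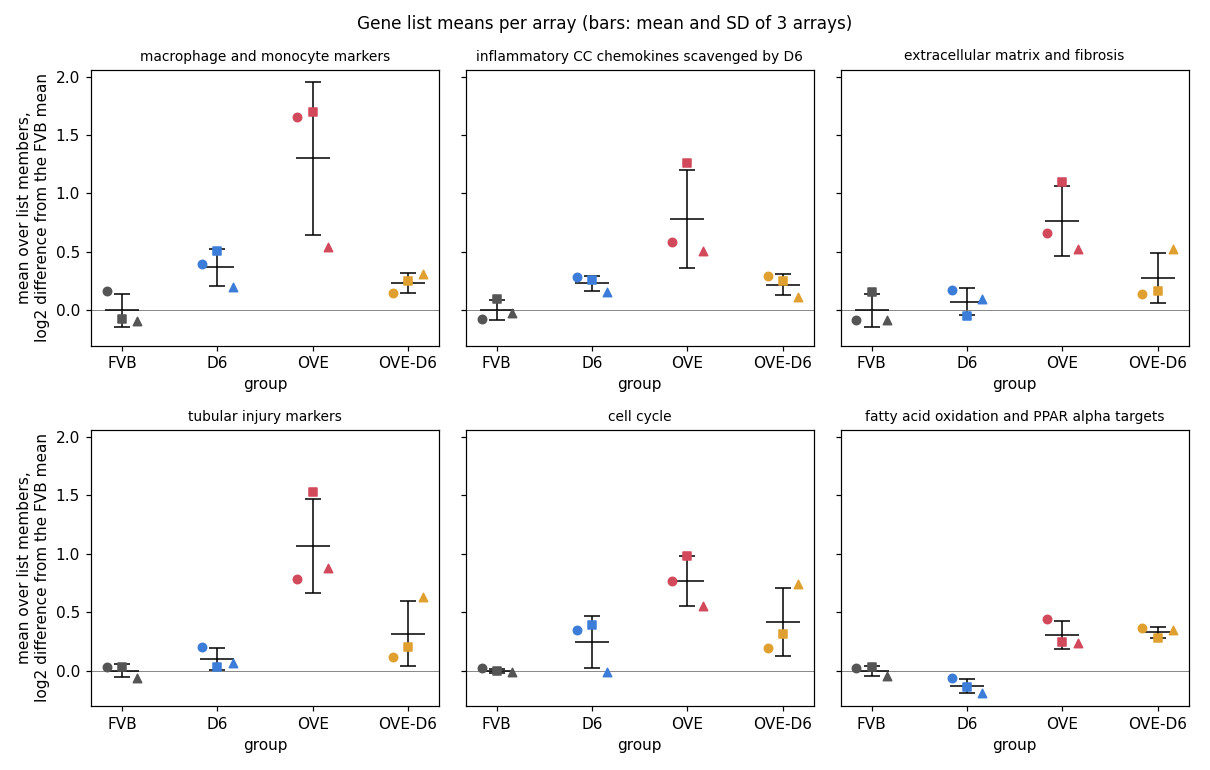
Mean log2 difference from the FVB mean over the members of 6 gene lists (vertical axis), with 1 point per array by group (horizontal axis, circle, square and triangle for replicates 1, 2 and 3) and bars for the mean and SD of 3 arrays. For macrophage and monocyte markers the OVE arrays lie between 0.55 and 1.70 and the OVE-D6 arrays between 0.15 and 0.31. For fatty acid oxidation and PPAR alpha targets the OVE and OVE-D6 means are 0.31 and 0.33.

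The comparison of OVE-D6 with OVE asked what loss of D6 did to the diabetic kidney. Macrophage and monocyte markers were lower as a list in the diabetic knockouts, though 3 of 21 passed over all genes and the list call did not hold with an estimated correlation. Cd14, the endotoxin co-receptor, was 2.32-fold lower (log2 -1.22 ± 0.13, SE, n = 3 per group, adjusted p = 0.00624), Lyz2 3.82-fold lower, Mrc1, the mannose receptor, 2.34-fold lower, and Mmp12, the macrophage elastase, 2.71-fold lower. Cd44 and Vcam1, adhesion molecules counted among the injury markers, were 3.00-fold and 2.59-fold lower. Ccr2, the receptor through which monocytes follow Ccl2, also differed (log2 -2.18 ± 0.26, adjusted p = 0.00879), but it is the 30th tested gene after Ackr2. Its OVE-D6 mean of 5.21 lay under 5.93, the 95th percentile of olfactory receptor genes, so the size of its change is not exact. In D6 against FVB Ccr2 differed by -0.01 ± 0.26, with both group means (5.84 and 5.83) also under 5.93. Without the genes beside Ackr2, the chemokine receptor list went from a median of -0.22 (adjusted p = 0.019) to -0.002 (adjusted p = 0.538). The genes left out include the receptor genes Ccr2 and Cx3cr1 (log2 -0.60, and 0.23 in D6 against FVB). The end of that call therefore does not show that the locus was its source. Genes that rose were Slc6a20a (1.64-fold), Cited1 (1.60-fold), Pvalb (1.56-fold) and Pcsk1n (1.38-fold). Klk14 and Ddx43 were also called as higher (log2 0.65 and 0.62), but all 4 group means of both, from 4.803 to 5.638 and from 5.172 to 5.874, lay under 5.93, so the size of these changes is uncertain.

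Of 21 macrophage and monocyte markers 3 fell (20 adjusted over the list alone), with a median log2 difference of -1.11 and adjusted p = 5.74e-20 (adjusted p = 0.234 with an estimated correlation). The D6-scavenged chemokines had a median of -0.54, with none of 8 past the threshold over all genes and 6 lower adjusted over the list alone, and a camera adjusted p of 5.89e-05 (adjusted p = 0.234 with an estimated correlation). Ccl2 differed by -1.34 ± 0.32 (adjusted p = 0.108), Ccl17 by -0.84 ± 0.23 and Ccl5 by -0.82 ± 0.27 on the log2 scale, and these did not pass. Tubular injury markers fell in 2 of 18 cases (12 adjusted over the list alone), with a median of -0.49 and adjusted p = 5.89e-12 (adjusted p = 0.234 with an estimated correlation). None of 30 extracellular matrix genes passed over all genes and 15 were lower adjusted over the list alone, with a median of -0.46 and adjusted p = 3.94e-13 (adjusted p = 0.234 with an estimated correlation). Complement genes fell in 1 of 12 cases (7 adjusted over the list alone), the receptor gene C5ar1 at log2 -0.74 ± 0.11, with adjusted p = 4.14e-07 (adjusted p = 0.234 with an estimated correlation). Of 16 other chemokines 1 fell (10 adjusted over the list alone), Ccl9 at 2.71-fold, with a median of -0.39 and adjusted p = 2.12e-06 (adjusted p = 0.234 with an estimated correlation). Without OVE replicate 2 the median was -0.293 for tubular injury markers, -0.281 for extracellular matrix genes and -0.333 for the D6-scavenged chemokines, and without OVE replicate 3 it was -0.647 for other chemokines. These calls held.

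Respiratory chain genes moved the other way as a list. All 25 had positive estimates, none passed over all genes or adjusted over the list alone, and the median was 0.12 with adjusted p = 1.56e-05 (adjusted p = 0.275 with an estimated correlation), or 0.076 without OVE replicate 2 (adjusted p = 0.0046). Proximal tubule transporters had a median of 0.12 over 25 genes, with 1 lower adjusted over the list alone and adjusted p = 0.00437 (adjusted p = 0.234 with an estimated correlation). Loop, distal tubule and collecting duct markers had a median of 0.14 over 23 genes, with 1 higher (2 adjusted over the list alone) and adjusted p = 0.0222 (adjusted p = 0.234 with an estimated correlation). With only the 2 groups compared that call ended (adjusted p = 0.0594, the highest over the alternatives that kept camera's preset correlation).

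The comparison held 8 higher and 30 lower genes, 38 in all, with 2438 at an unadjusted p under 0.05 where chance gives 824. Single-gene calls were fragile here. The count was 4, 5 and 5 without FVB replicate 1, 2 or 3, and 6, 5 and 4 without D6 replicate 1, 2 or 3. It was 16, 6 and 661 without OVE replicate 1, 2 or 3, and 1, 1 and 19 without OVE-D6 replicate 1, 2 or 3. A fit of these 2 groups alone gave 0.

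Without diabetes, 2 genes differed between D6 and FVB by limma, both lower in D6 and both near Ackr2 on chromosome 9. Slc6a20b was 2.44-fold lower (log2 -1.29 ± 0.09, SE, n = 3 per group, adjusted p = 6.35e-05), and Lars2, the mitochondrial leucyl-tRNA synthetase gene, was 1.75-fold lower (log2 -0.81 ± 0.09, adjusted p = 0.00436). The other genes with the smallest p did not pass: Ddx43, near background, at log2 0.68 ± 0.10 (adjusted p = 0.0699), Sacm1l at -0.53 ± 0.09, Cytl1 at -0.55, Camk1g at 0.65, Sectm1b at 0.52 and Fbxl2 at 0.51. At an unadjusted p under 0.05 there were 630 genes where chance gives 824.

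No macrophage and monocyte marker passed, over all genes or adjusted over the list alone, but all 21 had positive estimates in D6 against FVB, with a median of 0.37 and adjusted p = 3.61e-06 (adjusted p = 0.559 with an estimated correlation). All 19 cell cycle genes also had positive estimates, with a median of 0.26 (0.412 without D6 replicate 3) and adjusted p = 4.61e-06 (adjusted p = 0.559 with an estimated correlation). The D6-scavenged chemokines had a median of 0.26, all 8 with positive estimates and none past the threshold over all genes or the list alone, and adjusted p = 0.012 (adjusted p = 0.559 with an estimated correlation). That call ended without FVB replicate 1 or 3 or D6 replicate 1 or 2 (adjusted p = 0.119, 0.0813, 0.06 and 0.0536). The median was 0.32 for MHC class II genes (adjusted p = 9.07e-06, with medians from 0.318 to 0.654 over the alternatives) and 0.26 for other chemokines (adjusted p = 0.0065). It was 0.18 for complement (adjusted p = 0.012), 0.11 for T and NK cell markers (adjusted p = 0.012) and -0.10 for endothelial markers (adjusted p = 0.00108), and these 3 calls ended without D6 replicate 2 (adjusted p = 0.0877, 0.42 and 0.12). The T and NK call also ended without FVB replicate 3 (adjusted p = 0.101), and its median was 0.189 without FVB replicate 1 and 0.162 without D6 replicate 3. Fatty acid oxidation and PPAR alpha targets had a median of -0.11 and adjusted p = 3.85e-05 (adjusted p = 0.559 with an estimated correlation). Fat tissue markers had a median of -0.37 over 11 genes, none past the threshold, and adjusted p = 0.00487 (adjusted p = 0.559 with an estimated correlation). Their means on the FVB arrays ran from -1.13 to 0.92, and the call ended without FVB replicate 2, D6 replicate 1 or D6 replicate 2 (adjusted p = 0.548, 0.06 and 0.0515). The median was -0.187 without the first or second of these and -1.014 without FVB replicate 1. Fat taken with the kidney was not tested as a source of either difference. Camera called 10 of 33 lists, 5 without D6 replicate 2. It called 0 with an estimated correlation, and fry called 0.

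In knockouts, genes of fatty acid use rose with diabetes. Pdk4 was 3.35-fold higher in OVE-D6 than in D6 (log2 1.75 ± 0.24, SE, n = 3 per group, adjusted p = 0.00992), Angptl4 2.70-fold, the acyl-CoA thioesterase gene Acot1 1.90-fold and Decr1, which handles unsaturated fatty acids, 1.40-fold. Of 23 fatty acid oxidation and PPAR alpha targets 5 rose (15 adjusted over the list alone), with a median of 0.43 and adjusted p = 2.2e-20 (adjusted p = 0.0603 with an estimated correlation). Fry gave this list an adjusted p of 0.00293. Cyp4a12a and Cyp4a12b, fatty acid hydroxylase genes, were 5.53-fold and 4.99-fold higher, but these near-identical copies can share probe signal and are uncertain as separate genes. Other genes that rose most were Serpina6, the corticosteroid-binding globulin gene, at 9.20-fold, Aldh1a7 at 3.01-fold and Mtarc1 at 2.84-fold.

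The calcium-sensing receptor gene Casr fell by 0.87 ± 0.09 on the log2 scale in OVE-D6 against D6 (adjusted p = 0.00147), and Sec14l3 fell by 1.51, Fcamr by 0.90, Anxa13 by 0.89, Akr1c20 by 0.82 and Tprg, with an OVE-D6 mean of 5.54 near background, by 0.78. Srebf1 fell by 0.66 ± 0.12. Cholesterol and fatty acid synthesis genes fell in 1 of 19 cases (6 adjusted over the list alone), with a median of -0.21 and adjusted p = 0.000391 (adjusted p = 0.254 with an estimated correlation). That median was -0.133 without D6 replicate 2 and -0.075 without OVE-D6 replicate 1, where the call held. Macrophage and monocyte markers had a median of -0.13, with none of 21 past the threshold over all genes or adjusted over the list alone (camera adjusted p = 0.278). For the D6-scavenged chemokines the median was -0.01 (adjusted p = 0.881), with 1 of 8 lower adjusted over the list alone. MHC class II genes were lower as a list (median -0.30, adjusted p = 0.01), a call that ended with the filter at the 50th percentile (adjusted p = 0.075). Extracellular matrix, tubular injury and cell cycle genes were higher as lists, with medians of 0.15, 0.20 and 0.13 and adjusted p = 0.00168, 0.0144 and 0.0144. Without OVE-D6 replicate 3 these 3 calls ended, at medians of 0.015, 0.102 and 0.024 (adjusted p = 0.202, 0.329 and 0.722), and without OVE-D6 replicate 1 the medians were 0.268, 0.312 and 0.264. Without D6 replicate 3 the injury and cell cycle calls ended (adjusted p = 0.0534 and 0.69, medians 0.227 and 0.025), and with the filter at the 50th percentile the cell cycle call did (adjusted p = 0.0527). The cell cycle median lay between 0.212 and 0.219 without D6 replicate 1 or 2 or OVE-D6 replicate 2. None of these 4 lists passed with an estimated correlation (adjusted p = 0.679 each) or had a member past the threshold over all genes.

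In all, 30 genes were higher and 17 lower in OVE-D6 than in D6, 47 in total, with 1645 at an unadjusted p under 0.05 where chance gives 824. The count was 22, 18 and 17 without D6 replicate 1, 2 or 3, 19, 25 and 17 without OVE-D6 replicate 1, 2 or 3, and 74 without OVE replicate 3.

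Whether the diabetes effect differed between genotypes was tested as the interaction. No gene passed by limma, with a smallest adjusted p of 0.173 and 1647 genes at an unadjusted p under 0.05 where chance gives 824. The 8 genes with the smallest p, none past the threshold, were Lyz2 (log2 -2.76 ± 0.48), Ccr2 (-2.17 ± 0.37), Cd14 (-1.27), Csf2rb (-1.19), the macrophage growth factor gene Csf1 (-1.15), Fcgr3 (-1.04), C5ar1 (-0.91) and Tgfbi (-0.84). As a group, macrophage and monocyte markers had a median interaction of -1.46, with 0 of 21 past the threshold over all genes and 19 lower adjusted over the list alone. Their camera adjusted p was 1.5e-23 (adjusted p = 0.195 with an estimated correlation). MHC class II genes had a median of -1.08, with 10 of 11 lower adjusted over the list alone and adjusted p = 1.51e-08 (adjusted p = 0.22 with an estimated correlation). The D6-scavenged chemokines had a median of -0.81, with 6 of 8 lower adjusted over the list alone and adjusted p = 3.6e-06 (adjusted p = 0.195 with an estimated correlation). Without D6 replicate 1 the count of genes was 1, and without OVE replicate 3 it was 375.

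Over the 1260 genes called for the average diabetes effect, the median effect in its own direction was 0.45 on the log2 scale in wild types and 0.26 in knockouts. The median interaction was -0.16, and 78.3% of these genes had the smaller effect in knockouts (exact two-sided permutation p = 0.035 over 400 assignments, of which the smallest possible is 0.005). This p was 0.05, no longer past the threshold, with arrays centred on their medians or with array quality weights, and 0.09 over the 214 genes with an average effect of at least 1.5-fold. It was 0.14 and 0.15 without D6 replicate 1 or 3, and 0.07 and 0.08 without OVE-D6 replicate 1 or 2. Across genes, which are not independent replicates, the 2 diabetes effects, which share no array, had a Pearson r of 0.383 and a Spearman rho of 0.352. They had 26 genes higher in both, where independent lists give 1.47, and 14 lower in both, where they give 0.404.

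The knockout effects in non-diabetic and diabetic kidneys, which also share no array, had r = -0.143 and rho = -0.055 across genes. Of the 30 genes lower in OVE-D6 than in OVE, 27 were higher in OVE than in FVB, where independent lists give 1.47. Those 2 comparisons share the OVE arrays. Their covariance was -0.0421 against -0.00748 simulated with no effect, a difference of -0.0346, and their correlation was -0.727 against a simulated -0.501. Part of the excess overlap may come from the shared arrays.

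Averaged over disease state, 5 genes differed between the genotypes, all on chromosome 9. Slc6a20b (log2 -1.12 ± 0.06, SE, 6 arrays per genotype, adjusted p = 5.37e-06), Lars2 (-0.71 ± 0.06) and the phosphoinositide phosphatase gene Sacm1l (-0.43 ± 0.06) were lower in knockouts. Ddx43, a helicase gene with all 4 group means under 5.93 (0.65 ± 0.07, adjusted p = 0.00301), and Slc6a20a (0.64 ± 0.09) were higher in knockouts. Slc6a20a and Slc6a20b are neighbouring related copies, so their probe signals can be shared and are uncertain as separate genes. Lars2, Sacm1l, Slc6a20b and Slc6a20a are the 21st, 23rd, 24th and 25th tested genes after Ackr2. At an unadjusted p under 0.05 there were 1365 genes where chance gives 824. The count was 3 without each array of FVB, without D6 replicate 2 or 3, and without OVE-D6 replicate 1 or 2, and 112 without OVE replicate 3.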

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

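The tests on array scaling, single OVE arrays, macrophage markers, swapped labels and the neighbourhood of Ackr2 were chosen after the results were seen. The comparison of Ackr2 with olfactory receptor genes and the counts over other splits were fixed before their results were seen.

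Limma called 0 genes for a difference in the diabetes effect between the genotypes (1647 at an unadjusted p under 0.05), while a median over genes and 16 gene lists passed a test of that difference. The median difference over the genes called for the average effect was -0.159 on the log2 scale (exact permutation p = 0.035). Its permutation p did not pass with median centring or array quality weights (0.05 each), over genes of at least 1.5-fold (0.09), without D6 replicate 1 or 3 (0.14 and 0.15) or without OVE-D6 replicate 1 or 2 (0.07 and 0.08). For gene lists, the diabetes effect in knockouts minus that in wild types had a median log2 of -1.46 for macrophage and monocyte markers, -1.084 for MHC class II genes, -0.81 for D6-scavenged chemokines, -0.778 for other chemokines and -0.657 for complement. It was -0.624 for cell cycle, -0.541 for tubular injury, -0.525 for interferon-induced genes, -0.517 for extracellular matrix, -0.276 for chemokine receptors and -0.263 for immediate early genes. It was -0.261 for T and NK cell markers, -0.117 for NADPH oxidase genes, 0.103 for the respiratory chain, 0.111 for proximal tubule transporters and 0.147 for fatty acid oxidation. These list calls used camera's preset correlation, and none held with an estimated correlation or by fry. Without the genes beside Ackr2, which include the receptor genes Ccr2 and Cx3cr1, the chemokine receptor median was 0.032 and no longer passed (adjusted p = 0.454). That call also ended without D6 replicate 2 (adjusted p = 0.0556). The immediate early call ended without OVE replicate 3 or FVB replicate 3 (adjusted p = 0.159 and 0.0844), the NADPH oxidase call without D6 replicate 2 or OVE replicate 1 (0.075 and 0.0565), and the respiratory chain call without OVE replicate 2 (0.157). The proximal tubule call ended without FVB replicate 3, D6 replicate 1 or 2, OVE replicate 1 or OVE-D6 replicate 1, with adjusted p from 0.0536 to 0.0931. Without OVE replicate 1 the medians were -0.625 for MHC class II, -0.242 for interferon-induced genes, -0.131 for chemokine receptors, 0.065 for proximal tubule transporters and 0.229 for fatty acid oxidation. Without OVE replicate 2 they were -0.28 for extracellular matrix and 0.054 for the respiratory chain, and without OVE replicate 3 they were -0.398 for T and NK cell markers, -0.155 for immediate early genes and 0.187 for proximal tubule transporters. The immediate early median was -0.106 without FVB replicate 3 and -0.416 without FVB replicate 2, and the NADPH oxidase median was -0.24 without OVE-D6 replicate 1. Over all alternatives the NADPH oxidase median ran from -0.497 to -0.078. Among 100 of the splits of the arrays between genotypes within each disease state, the real one included, 14 gave as many lists as the real 16, with 19 the highest of the others. Chance is therefore not excluded for that count. For the count of genes, the real value was 0, which all 100 splits matched, with 3 the highest of the others.

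Probe sets without 1 gene symbol were outside the comparisons. Of 9561 tested, 1 was higher in OVE than in FVB and 1 was higher in OVE-D6 than in D6.

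Some genes beside Ackr2 differed between the genotypes: Lars2, Sacm1l, Slc6a20b and Slc6a20a did so in the same direction with and without diabetes, each at an unadjusted p under 0.01, while Ccr2 differed by -0.012 without and -2.185 with it. In a stretch of 81 tested genes, up to 50 on each side of Ackr2, 9 had an unadjusted p under 0.01 for the averaged knockout effect (8 without Ccr2). Of 14865 other stretches of that size, 0.0135% had as many (0.0336% without Ccr2). These stretches overlap each other, and some overlap the one beside Ackr2, so the shares are not exact probabilities. The cluster beside Ackr2 could come from donor DNA carried with the deleted locus. Whether a response spread over the genome adds to it cannot be told apart: of the 5 genes called for the averaged effect 0 lay off chromosome 9 (Ddx43 lay on it outside the stretch), but 112 genes were called without OVE replicate 3, and 32 of the 38 called in OVE-D6 against OVE lay off it. A local effect of the deletion on its neighbours stays open and was not tested, and sequence differences between strains could also alter probe binding.

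Macrophage and monocyte markers were lower in OVE-D6 than in OVE as a list, though 3 of 21 passed over all genes and the list did not pass with an estimated correlation (adjusted p = 0.234). With arrays centred on their medians their median was -1.097. The array medians lay between 6.84 and 6.93, so shifts of whole arrays are too small to give this difference. Centring could therefore move it little, and it says nothing of scaling that depends on intensity. Over 22 alternatives, with quantile normalisation among them, the median of this list ran from -1.467 to -0.894. Leaving out each OVE array in turn gave -0.894 or lower, which argues against a single OVE array for this list. Of 21 such markers, 20 had negative estimates, as fewer macrophages in the diabetic knockout kidney could give. Lower expression per macrophage would give the same and stays open, as does a milder course of diabetes in these mice, which was not tested. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05: the real split alone (1 of 10) gave as many genes (38, highest other 1) and as many lists (20, highest other 16).

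Ackr2 gave similar signal in both genotypes. Its mean of 6.88 exceeded 98.9% of 1027 olfactory receptor genes, which kidney should hardly express, between their 95th and 99th percentiles of 5.93 and 6.9, so a signal near background cannot be told apart from weak expression. If the probe set measured the deleted part above background, swapped genotype labels would leave 2 levels of Ackr2 among the arrays, but the widest gap between its ordered values was 0.059. A swap therefore does not account for the similar signal, and if the probe set did not measure that part the gap says nothing of the labels. A probe set outside the deleted part stays open, since the deleted part was not used here.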

How the results depend on the processing

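Leaving out the genes beside Ackr2 in OVE-D6 against OVE was chosen after seeing the data. Genes changed in OVE against FVB were 535 with a 1.5-fold minimum, 2206 at an adjusted p under 0.10, 610 at an unadjusted p under 0.01 with 1.5-fold, and 440 with only the 2 groups compared. Those in OVE-D6 against OVE were 151 at an adjusted p under 0.10, 246 at an unadjusted p under 0.01 with 1.5-fold, 22 with each probe set by itself, 91 with array quality weights, 21 without the genes beside Ackr2, and 0 by limma with only the 2 groups compared, against 2438 at an unadjusted p under 0.05 in the fit of all groups. Those in D6 against FVB were 12 at an unadjusted p under 0.01 with 1.5-fold, 4 with array quality weights and 1 with only the 2 groups. Those in OVE-D6 against D6 were 112 at an adjusted p under 0.10, 107 at an unadjusted p under 0.01 with 1.5-fold, 76 with trend and robust eBayes and 87 with array quality weights. The interaction had 274 at an unadjusted p under 0.01 with 1.5-fold. The averaged knockout effect had 12 at an adjusted p under 0.10, 29 at an unadjusted p under 0.01 with 1.5-fold, 8 with array quality weights and 1 without the genes beside Ackr2. Camera with an estimated correlation called 0 lists in each of the 6 comparisons. Fry called 12 lists in OVE against FVB, 7 in OVE-D6 against OVE and 1 in OVE-D6 against D6. It called 0 in D6 against FVB, the interaction and the averaged effect. The size of the diabetes effect in knockout against wild type was -0.409 (exact permutation p = 0.09) over genes of at least 1.5-fold, -0.158 (p = 0.05) with median centring and -0.173 (p = 0.05) with array quality weights. Ccl11 in OVE-D6 against OVE turned to 0.003 with median centring. Outside the thresholds and the 2-group fit, whose construction moves counts, the cause was not tested. Where a group mean lay under 5.93, the 95th percentile of olfactory receptor genes, as for Ccr2 in OVE-D6 at 5.21, the size of a change is not exact.

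Same-numbered arrays did not deviate together (correlations from -0.127 to 0.088). This gave no sign that the numbers pair the mice, though a weak pairing cannot be excluded. With a replicate block the count was 7 in OVE-D6 against OVE, 29 in OVE-D6 against D6 and 3 for the averaged effect, and the others stayed within 1.5 times.

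Leaving out each array in turn, with a group of 2 assumed to vary like the others, gave 353 to 1896 genes in OVE against FVB, 1 to 661 in OVE-D6 against OVE, 2 to 3 in D6 against FVB, 17 to 74 in OVE-D6 against D6, 0 to 375 for the interaction and 3 to 112 for the averaged effect. The highest counts of 1896, 661, 74, 375 and 112 came without OVE replicate 3. Lists ranged from 14 to 16, 16 to 20, 5 to 11, 8 to 16, 13 to 21 and 8 to 16 in the same order. Ackr2 ranged from -0.16 to -0.068 in D6 against FVB and from -0.01 to 0.103 in OVE-D6 against OVE. The correlation of the diabetes effects ranged from 0.29 to 0.425, that of the knockout effects from -0.195 to -0.038, and the size difference from -0.274 to -0.128. Near 0 and past no threshold, Ccl4 ranged from -0.028 to 0.104 in OVE against FVB and from -0.074 to 0.031 in OVE-D6 against OVE, and Ccl11 from -0.078 to 0.09 in OVE-D6 against OVE and from -0.163 to 0.135 for the interaction.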

Other observations

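Other immune lists also rose in OVE against FVB by camera at its preset correlation. T and NK cell markers had a median log2 difference of 0.27, with 1 of 13 higher over all genes, the T cell receptor component Cd3g at 1.89-fold from an FVB mean near the level of olfactory receptor genes, and 5 adjusted over the list alone (adjusted p = 0.00128, and adjusted p = 0.341 with an estimated correlation). MHC class II genes had a median of 0.89, with Cd74 3.01-fold and H2-Aa 2.05-fold higher, 2 of 11 over all genes and 6 adjusted over the list alone (adjusted p = 0.000226, and adjusted p = 0.352 with an estimated correlation). Their means on OVE replicates 1, 2 and 3 were 1.20, 0.86 and 0.07, and without OVE replicate 1 the median was 0.43 (adjusted p = 0.00836). Interferon-induced genes had a median of 0.46, with Oasl2 1.67-fold and Oas2 1.48-fold higher, 2 of 16 over all genes and 3 adjusted over the list alone (adjusted p = 0.00142, and adjusted p = 0.352 with an estimated correlation), and the median was 0.281 without OVE replicate 1 (adjusted p = 0.0293). Immediate early genes had a median of 0.21, with Myc 2.25-fold and Klf6 1.67-fold higher, 2 of 16 over all genes and 3 adjusted over the list alone (adjusted p = 0.0106, and adjusted p = 0.359 with an estimated correlation). The immediate early list no longer passed without OVE replicate 3 (adjusted p = 0.26) or without FVB replicate 3 (adjusted p = 0.188), where its median was 0.032. It was 0.315 without FVB replicate 2.

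Lists that did not pass in OVE against FVB included NADPH oxidase genes (adjusted p = 0.0632), of which 5 of 9 rose, among them Cybb, the catalytic subunit in phagocytes, at 2.47-fold. The adjusted p was 0.209 for chemokine receptors, 0.105 for B and plasma cell markers, 0.564 for neutrophil markers, 0.763 for endothelial markers, 0.524 for proximal tubule transporters, 0.7 for gluconeogenesis and 0.0632 for glycolysis. It was 0.0632 for antioxidant and NRF2 targets, 0.487 for the respiratory chain, 0.579 for the renin-angiotensin system, 0.487 for the unfolded protein response, 0.995 for clock genes and 0.519 for the genes beside Ackr2. Markers of tissues that could adhere to the kidney did not pass either, at 0.519 for fat and 0.519 for adrenal markers. Lists of male-biased and female-biased kidney genes stood at 0.487 and 0.21. Blood cell genes, with 4 tested members and a median of -0.41, and sex chromosome genes, with 1 tested member at -0.08, were too few for the list test.

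Beside the changes in OVE-D6 against OVE, adrenal markers had a median of 0.29 (adjusted p = 0.00866, and adjusted p = 0.248 with an estimated correlation), with none of 8 past the threshold. Their mean was 1.189 on OVE-D6 replicate 3 and 0.014 and 0.012 on the other OVE-D6 arrays. That call ended without OVE-D6 replicate 3 (median 0.065, adjusted p = 0.299) or OVE replicate 3 (adjusted p = 0.0617). A difference in adrenal tissue taken with the kidney was not tested. Among the immune lists lower in OVE-D6 by camera at its preset correlation, none passed with an estimated correlation. Without OVE replicate 1 the calls ended for T and NK cell markers (median from -0.171 to -0.137, adjusted p = 0.0539), B and plasma cell markers (from -0.221 to -0.164, adjusted p = 0.0502) and chemokine receptors (from -0.219 to -0.032, adjusted p = 0.1). The first 2 medians thus moved little with that array, and the B and plasma median was -0.117 without OVE replicate 2. Without OVE replicate 3 the medians were -0.259, -0.454 and, for MHC class II, -1.109, and without OVE-D6 replicate 3 the chemokine receptor call ended at -0.14 (adjusted p = 0.0898). Without OVE replicate 1 the medians went from -0.727 to -0.335 for MHC class II and from -0.462 to -0.154 for interferon-induced genes.

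Further lists were called by camera at its preset correlation, and none of them with an estimated correlation. In OVE-D6 against OVE the median was -0.357 for cell cycle (adjusted p = 2.12e-06), -0.151 for the unfolded protein response (0.00852), -0.082 for immediate early genes (0.0354), -0.084 for NADPH oxidase genes (0.0441) and 0.206 for the renin-angiotensin system (0.0441). Counts of alternatives here and below leave out camera with an estimated correlation and fry. Of 22 alternatives the cell cycle call held in 22, and the others in 21, 18, 15 and 12 in that order. The highest adjusted p of those others was 0.204, 0.563, 0.113 and 0.223. Leaving out 1 array moved the median by over 1.5 times, to -0.223 and -0.231 for cell cycle (without OVE-D6 replicate 1 or OVE replicate 2), to -0.244 for the unfolded protein response (without OVE replicate 1), and for immediate early genes to -0.181, -0.046, -0.131 and -0.125 (without OVE replicate 1 or 3 or OVE-D6 replicate 2 or 3). It was -0.22, -0.045 and -0.129 for NADPH oxidase genes (without OVE-D6 replicate 1, 2 or 3), and 0.114, 0.128 and 0.129 for the renin-angiotensin system (without OVE replicate 2 or 3 or OVE-D6 replicate 2). Over all 22 alternatives the NADPH oxidase median ran from -0.423 to -0.045. In OVE-D6 against D6 the median was 0.135 for endothelial markers, 0.128 for glycolysis, 0.091 for antioxidant and NRF2 targets, 0.068 for the respiratory chain, 0.059 for proximal tubule transporters and -0.138 for loop, distal tubule and collecting duct markers. Of 21 alternatives these calls held in 19, 18, 21, 19, 15 and 21. Without D6 replicate 2 the median was 0.075 for endothelial markers, 0.031 for proximal tubule transporters and -0.085 for the loop list, which was also -0.082 without D6 replicate 1 and -0.064 without OVE-D6 replicate 2, and without D6 replicate 3 it was 0.084 for glycolysis. For the averaged knockout effect 12 lists were called, of which macrophage markers (-0.349), tubular injury (-0.239), extracellular matrix (-0.198) and the respiratory chain (0.087) were called in 20 of 20 alternatives. Without OVE replicate 2 the median was -0.109 for tubular injury, -0.089 for extracellular matrix and 0.048 for the respiratory chain, and without OVE replicate 3 it was -0.547 for macrophage markers. The calls of the other 8 ended in at least 1. Averaging hid opposite directions for macrophage markers, with medians of 0.372 in D6 against FVB and -1.112 in OVE-D6 against OVE. List means for tubular injury and extracellular matrix were not lower in D6 than in FVB (0.098 and 0.075 against 0). Their medians were -0.488 and -0.455 in OVE-D6 against OVE. Respiratory chain means were higher in D6 than in FVB (0.031 against 0) and in OVE-D6 than in OVE (0.094 against -0.039).

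A hypothesis chosen after the results were seen was that the rise of Cyp4a12a and Cyp4a12b, which male mouse kidneys express more, might come from male tissue or from a general shift of male-biased genes. All 12 arrays had Xist between 12.53 and 12.87 and the Y-linked genes Kdm5d, Eif2s3y and Uty at or below 5.33, against a limit of 8 set for both, so male tissue is argued against. A general shift of the male-biased list cannot be told apart from a change of single genes, since 7 of its 12 members had positive estimates in each diabetic comparison. The list mean was 0.234 (0.165 to 0.336) on the OVE-D6 arrays against -0.095 (-0.136 to -0.035) on the D6 arrays, and 0.189 in OVE against 0 in FVB, though camera did not call it (adjusted p = 0.223 and 0.487).

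Other splits of the arrays were counted for each comparison. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. In OVE against FVB the real split alone (1 of 10) gave 1200 genes, with 0 the highest of the others, while 4 of 10 splits gave at least its 14 lists, with 16 the highest of the others. In D6 against FVB the real split alone (1 of 10) gave 2 genes, with 1 the highest of the others, and 10 lists, with 7 the highest. In OVE-D6 against D6 the real split alone (1 of 10) gave 47 genes, with 0 the highest of the others, and 12 lists, with 8 the highest. For the averaged knockout effect, 1 of 100 splits, the real one, reached 5 genes, with 3 the highest of the others. That share is under 0.05 and argues against chance for the count of 5. Leaving out 1 array brought the count as low as 3, and the splits were not repeated for those fits. Lars2, Sacm1l, Slc6a20b and Slc6a20a among the 5 lie close together and need not be independent. For the 12 lists of the averaged effect, 33 of 100 splits gave as many, with 21 the highest of the others, so chance is not excluded there.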
